A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

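Total RNA of Saccharomyces cerevisiae was labelled with Cy5 in channel 1 and Cy3 in channel 2 on every array, with an Agilent low-input linear amplification kit, per the labels. The deposited table holds 1 log2 ratio per probe and array. The authors' normalization, the log base and any sign turning of dye-swapped arrays are not given in the sources used here. The values were taken as log2 because their size would be implausible in another base, so every fold rests on that reading. Array medians over genes ran from -0.188 to 0.296, and no further centring was applied.

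The platform annotation names 1 gene for each of 9271 probes, and 1536 probes are unnamed here. All 9271 identifiers matched the gene table of assembly R64, used for names only. Probes of a gene were averaged, which gave 5636 genes, 2026 with 1 probe, 3592 with 2 and 18 with 3 or 4. The probes of a gene differed by over 1 for 1 gene in raffinose, 3 in galactose and 4 in glucose. Genes needed a value on 3 of the 4 arrays of each sugar.

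The direction of the arrays was examined first. Over probes with a gene name all arrays correlated above 0, with r from 0.12 to 0.975 across genes. Within raffinose, r was 0.956 for replicates 1 and 2 and 0.942 for 3 and 4, but 0.243 to 0.466 between those pairs. Over all probes the latter fell to between -0.507 and -0.34 in raffinose, between -0.143 and -0.0513 in galactose and between 0.1 and 0.118 in glucose. The difference came with 114 unnamed spots of extreme ratio (over 5 in size on at least 6 arrays), all of which changed sign between replicates 1 and 2 (median -8.16) and 3 and 4 (median 7.91). Replicates 1 and 2 were therefore treated as 1 orientation and replicates 3 and 4 as the other, although the labels give the same dyes on all arrays. A rule set in advance said to turn arrays of a sugar that correlate below -0.3 across probes and to give no direction then. Read over all probes it applies to raffinose. It was instead applied to probes with a gene name, after these correlations were seen. This departs from the literal rule. With raffinose replicates 3 and 4 turned, gene counts are given for raffinose and its contrasts, and list calls and values of some lists and genes for raffinose alone.

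The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays, with 1 mean per sugar and a shared estimate of the spread. Each mean was tested against 0 and each pair of means against each other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The tests, the rule for named genes and 35 gene lists were chosen before the data were examined. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, again with an estimated correlation, and with fry as an alternative. Of 11 lists called in raffinose, 13 in galactose and 20 in glucose, 0 held with an estimated correlation; of 22, 16 and 19 called in the contrasts of raffinose with glucose, galactose with glucose and raffinose with galactose, 1, 0 and 0 held. Medians of lists called in single sugars are given by orientation where they differed in sign or by over 1.5 times. Overlaps of calls were compared with independent lists by Fisher's exact test.

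The rule for named genes took GCR1; the 12 highest and 12 lowest genes per sugar among those called, with the same sign on all 4 arrays and an unadjusted p under 0.05 in each of the 3 ways of averaging arrays in pairs; the glycolysis list; up to 4 called members of each called list; the 5 highest and 5 lowest genes of each contrast; and members of the strain marker, glycolytic regulator and galactose utilisation lists.

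Deviations of same-numbered arrays from their sugar means correlated across sugars at r = 0.521 to 0.893, so by the criterion fixed for pairing (over 0.1 for every pair) the numbers pair the arrays. What they share is the orientation: after its removal the range was -0.321 to 0.153. Even before its removal, 3 of 12 arrays correlated best with their own number. The fit with the replicate number as a block is given where it changed a call or moved a count by over 1.5 times.

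The fit was tested on simulated data for the raffinose comparison, with 200 of 5636 genes changed. With independent arrays it recovered 41.7%, 83.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and 9.09% of its calls were false. With dye-swap repeats sharing part of their variance, 34% of calls were false when arrays were fitted singly and 2.22% when repeats were averaged, which recovered 0%, 41.3% and 87.7%. With an orientation effect, 0% of calls were false when arrays were fitted singly and 5.95% when arrays were averaged across orientations, and genes changed by 0.5 were recovered in 16.2% and 42.6% of cases. Each simulation was a single draw, and shared variance and the orientation effect were not simulated together. The real fit called 2071 genes in raffinose, far more than the 200 changed here. The false shares therefore do not carry over to the real calls. Alternatives covered the averaging of arrays, blocks, centring, scaling, probes, missing values, thresholds and each array left out in turn. Array pairs that are dye-swap repeats are not labelled, so no single averaging was chosen.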

Results

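Dual-colour oligonucleotide arrays compared budding yeast carrying a null allele of GCR1, which encodes a transcriptional activator of glycolytic genes, with a second strain during growth on 3 sugars. Raffinose and galactose were supplied at 3% and glucose at 2%. Each sugar had 4 arrays, numbered 1 to 4, for 12 arrays in all. The design includes biological replicates and dye-swapped repeats of each, but which arrays repeat which culture is not labelled. The 4 arrays of a sugar are therefore fewer than 4 independent cultures, and p-values over arrays may be too small. The second strain is not named in the labels and was taken to be the GCR1 parent. Each value is a log2 ratio between the strains for 1 of 5636 genes, given below as the mean ± SD over 4 arrays. Spot brightness was not analysed here, so the signal over background behind each ratio is unknown, and the number of arrays limits the precision.

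GCR1 (YPL075W) itself read higher, not lower, in the strain labelled as the mutant. Its mean log2 ratio was 1.67 ± 0.35 in raffinose (limma, adjusted p = 1.9e-06), 1.58 ± 0.22 in galactose (adjusted p = 7.9e-07) and 0.40 ± 0.14 in glucose (adjusted p = 0.019), and it lay above 0 on all 12 arrays. The glucose call was lost without glucose replicate 1, 2 or 3 (adjusted p = 0.0662, 0.0705 and 0.0609). The labels do not say which channel held the mutant, and the position of the GCR1 probes relative to the deleted part is not known here. A positive ratio was taken as higher in the labelled mutant. This direction is not settled. Array titles name the mutant but not its channel, so they do not give this direction. It rests on the textbook role of Gcr1, since genes that Gcr1 is known to activate had negative ratios. The GCR1 probes, however, go against this direction. The opposite direction would exchange higher and lower in every statement below.

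The relative signs of the 4 raffinose arrays were examined apart from this. Over all probes, replicates 1 and 2 correlated with replicates 3 and 4 at r = -0.507 to -0.34, and 114 unnamed spots of extreme ratio changed sign between these pairs. Over probes with a gene name r was 0.243 to 0.466, and GPM1 lay between -6.17 and -4.60 on the 4 arrays. The means of replicates 1 and 2 and of replicates 3 and 4 had opposite signs for 2558 of 5636 genes. A rule set in advance would, read over all probes, have turned the signs of raffinose replicates 3 and 4. It was applied to probes with a gene name instead, a choice made after the correlations were seen. With those 2 arrays turned, limma called 0 genes in raffinose, with 1463 at an unadjusted p under 0.05; turning cancels any effect that both pairs share, so this count does not bear on which signs are right.

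In raffinose, the phosphoglycerate mutase gene GPM1 (YKL152C) and the enolase gene ENO2 (YHR174W) had the lowest ratios among the named genes, at -5.39 ± 0.88 and -5.05 ± 0.73 in the labelled mutant. The other enolase gene, ENO1 (YGR254W), was at -4.05 ± 0.54. Cytosolic ribosomal protein genes fell in 123 of 136 cases, while 26 of 37 genes of the environmental stress response and 19 of 37 respiratory chain genes rose. The highest ratio among the named genes was that of GPM2 (YDL021W), a homologue of GPM1, at 4.34 ± 0.18.

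Of the 17 genes on the glycolysis list, 10 fell, 2 rose and 5 did not pass the test in raffinose; adjusted over the list alone, 10 fell and 3 rose. Besides GPM1 and the enolases, the fallen genes included TDH3 (-2.52 ± 0.53), TPI1 (-2.24 ± 0.64), PGK1 (-2.18 ± 0.63) and the pyruvate kinase gene CDC19 (-2.35 ± 0.70). The genes that rose encode enzymes that phosphorylate glucose, GLK1 (1.29 ± 0.62) and HXK1 (0.73 ± 0.45). HXK1 lost its call without raffinose replicate 1 or 2 (adjusted p = 0.0872 and 0.0834). ENO1 and ENO2, like TDH2 and TDH3, are close paralogs, and cross-hybridisation between them cannot be excluded. The list was called lower (camera, adjusted p = 7.23e-05; adjusted p = 0.989 with an estimated correlation). Its median was -0.80 and -0.84 on replicates 1 and 2 against -1.98 and -1.77 on replicates 3 and 4.

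Of 136 cytosolic ribosomal protein genes, 123 fell in raffinose and 0 rose, with a median of -1.02; adjusted over the list alone, 134 fell (adjusted p = 7.12e-32). The median was -0.37 and -0.67 on replicates 1 and 2 against -1.52 and -1.44 on replicates 3 and 4. RPL11A (-1.86 ± 0.46) and RPS14B (-1.70 ± 0.38) were among the lowest. Among 56 mitochondrial ribosomal protein genes 29 fell and 2 rose (31 and 2 adjusted over the list alone; adjusted p = 7.13e-10), among them MRP2 (-1.56 ± 0.30), but the list's median was -0.057 and -0.23 on replicates 1 and 2 against -0.865 and -0.80 on replicates 3 and 4. Of 10 histone genes 8 fell (9 adjusted over the list alone; adjusted p = 3.37e-05), led by HTA1 (-1.36 ± 0.55), with medians of -0.28 and -0.67 against -1.46 and -1.28 on the same arrays. Of 44 cell wall genes 25 fell and 2 rose (29 and 2 adjusted over the list alone; adjusted p = 7.23e-10), with YPS3 at -1.99 ± 0.38 and medians of -0.54 and -0.48 against -1.30 and -0.98 there. Of 19 heat shock chaperone genes 9 fell and 2 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0104), but the list's median was 0.16 and 0.10 on replicates 1 and 2 against -1.003 and -0.80 on replicates 3 and 4, and fry, which asks whether a list's genes move 1 way, did not call it (adjusted p = 0.164). With an estimated correlation each of these lists had an adjusted p = 0.989.

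Of 37 genes of the environmental stress response 26 rose and 4 fell in raffinose, the same counts as when adjusted over the list alone (adjusted p = 3.77e-05), and MSC1 reached 2.45 ± 0.47. The list's median was 1.16 and 1.10 on replicates 1 and 2 against 0.38 and 0.53 on replicates 3 and 4. Of 37 respiratory chain and ATP synthase genes 19 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 3.37e-05), with ATP3 at 1.27 ± 0.37. The list's median was 1.06 and 0.86 on replicates 1 and 2 but 0.09 and 0.20 on replicates 3 and 4. In the tricarboxylic acid cycle 9 of 18 genes rose (9 adjusted over the list alone; adjusted p = 0.00393), led by the mitochondrial citrate synthase gene CIT3 at 3.70 ± 0.09. Here the medians were 0.97 and 0.96 on replicates 1 and 2 but 0.03 and 0.25 on replicates 3 and 4. Of 18 trehalose and glycogen genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00882), with medians of 0.77 and 0.81 on replicates 1 and 2 against 0.13 and 0.45 on replicates 3 and 4. Of 32 pheromone response genes 12 rose (12 adjusted over the list alone; adjusted p = 0.0382), with PRM1 at 2.20 ± 0.28, but this call was lost with arrays averaged across the orientations (adjusted p = 0.054 and 0.0627). Each of these lists too had an adjusted p = 0.989 with an estimated correlation. Other genes at the extremes were SPG4 (4.09 ± 0.39), IMD2 (3.85 ± 0.31), INM1 (3.28 ± 0.35) and URA3 (2.64 ± 0.11) above 0, and PET122 (-4.32 ± 0.66) and the phosphate transporter gene PHO89 (-3.11 ± 0.35) below it.

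In all, 2071 of 5636 genes were called in raffinose at an adjusted p under 0.05, 1265 higher and 806 lower (1436 higher and 1424 lower with each array centred on its median). Without raffinose replicate 1 the split was 874 higher and 848 lower, and without raffinose replicate 3 it was 1352 and 532. The count was 3406 with the replicate number as a block and 184 with replicates 1 and 2, and 3 and 4, averaged before the fit, but 3660 or 4558 when averages crossed those pairs.

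With raffinose replicates 3 and 4 turned, 41 of 76 called named genes changed sign and limma called 0 of them; the lowest adjusted p was 0.191. GPM1 was at 0.76, ENO2 at 0.63, ENO1 at 0.46 and GPM2 at 0.13. Camera called 12 lists, 2 of them among the 11 called without turning and both in the other direction. These were mitochondrial ribosomal proteins, now higher (median 0.344, adjusted p = 0.0326), and pheromone response, now lower although its median was 0.177 (adjusted p = 0.00528); with an estimated correlation they had an adjusted p = 0.96 and adjusted p = 0.794. The turned medians were 0.463 for glycolysis (adjusted p = 0.74), 0.478 for cytosolic ribosomal proteins (adjusted p = 0.11), 0.404 for the respiratory chain (adjusted p = 0.0574) and 0.325 for environmental stress (adjusted p = 0.63), and 0.313 to 0.451 for the other 5 called lists (adjusted p = 0.11 to 0.907). Of the 12 lists 1 held with an estimated correlation, hexose transport and sensing, as lower (adjusted p = 0.0493). As with the count of genes, turning cancels what both pairs share. What it leaves is the difference between replicates 1 and 2 and replicates 3 and 4. Turned alike, the glycolysis median was 0.463 in raffinose, 0.473 in galactose and 0.472 in glucose. With the deposited signs, the turned list directions describe that difference and not an effect of the deletion.

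**Figure D1:**
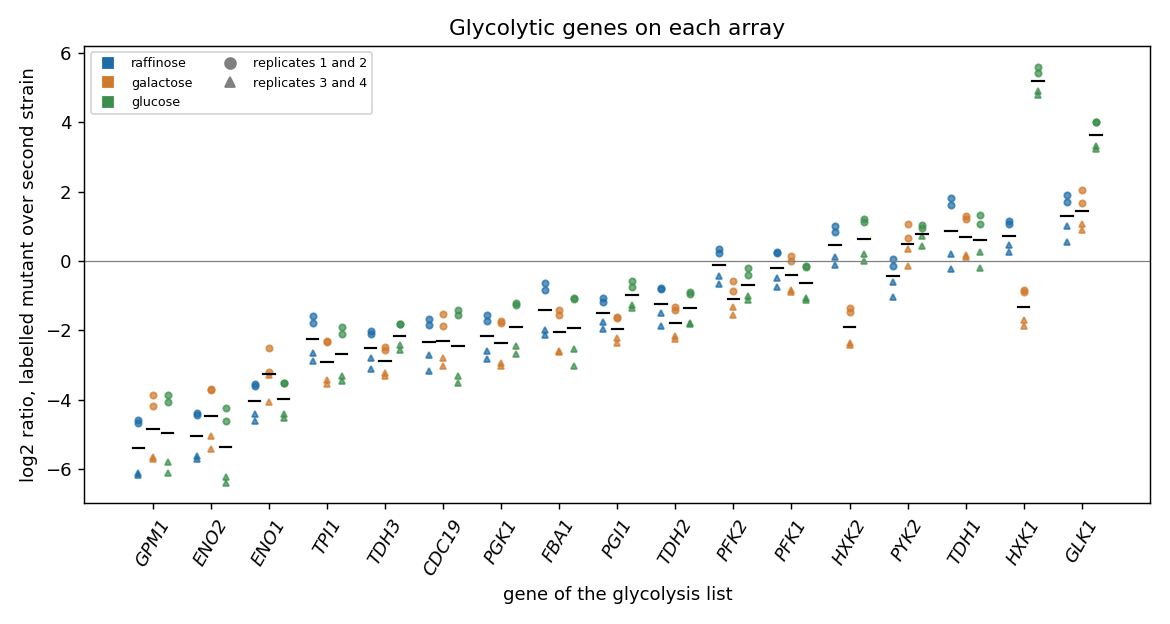
Log2 ratio (labelled mutant over second strain, y axis) of the 17 genes of the glycolysis list (x axis) on each of the 12 arrays; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the mean of 4 arrays. GPM1, ENO2 and ENO1 lie lowest in all 3 sugars, and HXK1 runs from -1.33 in galactose to 5.18 in glucose.

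In galactose, GPM1 and ENO2 fell again, and so did 7 of 11 genes for the use of sucrose and maltose. GPM1 was at -4.86 ± 0.97, ENO2 at -4.48 ± 0.90 and the invertase gene SUC2 at -4.44 ± 0.59. Ribosomal protein genes were lower in 135 of 136 cases in the cytosol and 50 of 56 in mitochondria, and 27 of 37 stress genes and the polyamine exporter gene TPO2 (5.48 ± 0.57) were higher. Of the 17 glycolysis genes 13 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -1.97; the list had an adjusted p = 5.21e-05, and an adjusted p = 0.911 with an estimated correlation. Its median was -1.41 and -1.57 on replicates 1 and 2 against -2.44 and -2.38 on replicates 3 and 4. HXK2, which encodes the main hexokinase of glucose-grown cells, was at -1.91 ± 0.58 and HXK1 at -1.33 ± 0.55, whereas GLK1 was at 1.43 ± 0.53.

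Of 9 galactose utilisation genes 5 fell in galactose and 0 rose, the same counts as when adjusted over the list alone (adjusted p = 0.0344; adjusted p = 0.715 with an estimated correlation). The galactokinase gene GAL1 had a ratio of -2.04 ± 0.71, the permease gene GAL2 -1.57 ± 0.79 and GAL7 -1.15 ± 0.62, while GAL10 (-0.69 ± 0.61) did not pass the test. The call of GAL4 was lost without galactose replicate 1 or 2 (limma, adjusted p = 0.0637 and 0.0887). That of GAL80 was lost without galactose replicate 3 or 4 (limma, adjusted p = 0.154 and 0.133). The galactose utilisation list lost its call when each array was centred on its median (camera, adjusted p = 0.0879). Its median was -0.18 and -0.27 on replicates 1 and 2 against -1.0 and -0.937 on replicates 3 and 4. Of 11 sucrose and maltose genes 7 fell (7 adjusted over the list alone; adjusted p = 0.000935), among them MAL12 (-3.55 ± 0.17) and MAL32 (-3.37 ± 0.14), close paralogs that their probes may not separate. Of 17 peroxisome and beta-oxidation genes 12 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.00156), with the catalase gene CTA1 at -2.76 ± 0.18 and medians of -0.36 and -0.48 on replicates 1 and 2 against -0.84 and -1.09 on replicates 3 and 4. With an estimated correlation both lists had an adjusted p = 0.715.

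Cytosolic ribosomal protein genes fell in 135 of 136 cases in galactose (135 adjusted over the list alone; adjusted p = 5.5e-34), with a median of -1.82. Mitochondrial ribosomal protein genes fell in 50 of 56 cases (52 adjusted over the list alone; adjusted p = 3.41e-18), with a median of -1.26. All 10 histone genes fell (10 adjusted over the list alone; adjusted p = 4.71e-05), with medians of -1.15 and -1.02 on replicates 1 and 2 against -1.78 and -1.76 on replicates 3 and 4. These 3 lists had an adjusted p = 0.715 with an estimated correlation. Respiratory chain and ATP synthase genes fell in 17 of 37 cases and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.00203), with CYC1 at -1.28 ± 0.50. Translation factor genes fell in 16 of 37 cases and rose in 2, with the same counts adjusted over the list alone (adjusted p = 0.0032). Amino acid biosynthesis genes fell in 24 of 54 cases and rose in 9 (24 and 10 adjusted over the list alone; adjusted p = 0.0151), and ergosterol genes fell in 8 of 25 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0262). These 4 lists had an adjusted p = 0.958 with an estimated correlation, and fry called none of them (adjusted p = 0.136, 0.149, 0.265 and 0.187). Their medians lay near 0 on replicates 1 and 2. Those of the respiratory chain were -0.11 and -0.11 against -0.81 and -0.67 on replicates 3 and 4, and those of translation factors -0.072 and -0.083 against -0.92 and -0.98. Amino acid biosynthesis had -0.0088 and 0.040 against -0.63 and -0.74, and ergosterol genes 0.025 and 0.033 against -0.73 and -0.69.

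Environmental stress genes rose in 27 of 37 cases in galactose and fell in 4, the same as when adjusted over the list alone, with the catalase gene CTT1 at 2.95 ± 0.42 and the disaggregase gene HSP104 at 2.61 ± 0.47 (adjusted p = 1.21e-05; adjusted p = 0.715 with an estimated correlation). Trehalose and glycogen genes rose in 14 of 18 cases and fell in 1, again the same adjusted over the list alone, with TSL1 at 2.25 ± 0.31 (adjusted p = 0.00179; adjusted p = 0.95 with an estimated correlation). Their median was 1.43 and 1.25 on replicates 1 and 2 against 0.86 and 0.63 on replicates 3 and 4. Pheromone response genes rose in 16 of 32 cases and fell in 2, the same adjusted over the list alone, and meiosis genes rose in 15 of 37 and fell in 1 (13 and 1 adjusted over the list alone). These lists were called higher with the replicate number as a block (adjusted p = 0.0288 and 0.0287, against 0.0806 and 0.0901; adjusted p = 0.715 and adjusted p = 0.958 with an estimated correlation). The pheromone median was 0.60 and 0.64 on replicates 1 and 2 against 0.33 and 0.29 on replicates 3 and 4. The meiosis median was -0.21 and 0.074 on replicates 1 and 2 but 1.085 and 1.238 on replicates 3 and 4. Single genes at the extremes were YRO2 (5.10 ± 0.16), the peroxisomal citrate synthase gene CIT2 (4.51 ± 0.37) and GPM2 (4.36 ± 0.16) above 0, and RGI2 (-5.05 ± 0.36), PET122 (-4.06 ± 0.95) and the hexose transporter gene HXT2 (-3.62 ± 0.63) below it.

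In all, 3383 genes were called in galactose, 1962 higher and 1421 lower (1976 and 1966 with each array centred). Averaging replicates 1 and 2, and 3 and 4, before the fit left 1688.

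In glucose, ENO2, GPM1 and all 85 ribosome biogenesis genes fell, and all 37 respiratory chain genes and 17 of 18 genes each of gluconeogenesis and of storage carbohydrate metabolism rose. ENO2 was at -5.37 ± 1.10 and GPM1 at -4.96 ± 1.15. The small heat shock protein gene HSP12 rose to 6.12 ± 0.40, GPM2 to 5.99 ± 0.21 and HXK1, a hexokinase gene normally repressed by glucose, to 5.18 ± 0.40. Of the 17 glycolysis genes 12 fell and 3 rose (12 and 4 adjusted over the list alone), with a median of -1.37. The calls of PFK1 and PFK2 as lower were lost without glucose replicate 3 or 4 (limma, adjusted p = 0.069 to 0.183). The list as a whole was not called (adjusted p = 0.0514, or 0.018 with the replicate number as a block; adjusted p = 0.852 with an estimated correlation). Its median was -0.90 and -0.96 on replicates 1 and 2 against -1.81 and -1.79 on replicates 3 and 4.

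All 37 respiratory chain and ATP synthase genes rose in glucose (37 adjusted over the list alone; adjusted p = 1.15e-14), with a median of 1.59 and CYC7 at 3.05 ± 0.18. In the tricarboxylic acid cycle 17 of 18 genes rose (17 adjusted over the list alone; adjusted p = 3.58e-08), with CIT1 at 3.79 ± 0.45. Of 18 trehalose and glycogen genes 17 rose (17 adjusted over the list alone; adjusted p = 3.58e-08), with GLC3 at 3.26 ± 0.11. These 3 lists had an adjusted p = 0.45 with an estimated correlation. Of 18 gluconeogenesis and glyoxylate cycle genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 2.3e-08), with the lactate permease gene JEN1 at 3.16 ± 0.19. Sucrose and maltose genes rose in 7 of 11 cases (7 adjusted over the list alone; adjusted p = 0.000813), with IMA1 at 2.04 ± 0.19, and hexose transport and sensing genes rose in 11 of 24 and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.00617), with HXT4 at 1.93 ± 0.13 and medians of 0.45 and 0.52 on replicates 1 and 2 against 0.97 and 1.03 on replicates 3 and 4. These 3 lists had an adjusted p = 0.315 with an estimated correlation.

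Environmental stress genes rose in 30 of 37 cases in glucose and fell in 2 (30 and 3 adjusted over the list alone; adjusted p = 3.95e-12, and adjusted p = 0.393 with an estimated correlation). Genes under nitrogen catabolite repression rose in 18 of 26 cases and fell in 2, the same adjusted over the list alone, with the ammonium permease gene MEP1 at 2.37 ± 0.07 (adjusted p = 3.49e-05; adjusted p = 0.153 with an estimated correlation). Peroxisome and beta-oxidation genes rose in 10 of 17 cases (10 adjusted over the list alone), with the thiolase gene POT1 at 3.77 ± 0.19 (adjusted p = 0.00103; adjusted p = 0.505 with an estimated correlation). Galactose utilisation genes rose in 6 of 9 cases (6 adjusted over the list alone), with GCY1 at 3.89 ± 0.14 and GAL1 at 1.16 ± 0.52 (adjusted p = 0.018; adjusted p = 0.472 with an estimated correlation). The list's median was 0.49 and 0.65 on replicates 1 and 2 against 1.36 and 1.26 on replicates 3 and 4. Sulfur and methionine genes rose in 14 of 28 cases and fell in 4, the same adjusted over the list alone, led by STR3 at 4.18 ± 0.47 (adjusted p = 0.0428; adjusted p = 0.793 with an estimated correlation). The call was lost when replicates 1 and 2, and 3 and 4, were averaged (adjusted p = 0.0512) or arrays were centred (adjusted p = 0.0629), and the median was 0.60 and 0.63 on replicates 1 and 2 against 0.35 and 0.23 on replicates 3 and 4. Meiosis genes rose in 12 of 37 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.811 with an estimated correlation). Their median was 0.032 and -0.0175 on replicates 1 and 2 but 1.145 and 1.324 on replicates 3 and 4. Seripauperin and anaerobic genes rose in 11 of 17 cases and fell in 4, the same adjusted over the list alone (adjusted p = 0.0223, or 0.0513 with replicates 1 and 3, and 2 and 4, averaged; adjusted p = 0.793 with an estimated correlation). The PAU genes among them are near-identical and cannot be separated with certainty.

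Ribosome biogenesis genes fell in all 85 cases in glucose (85 adjusted over the list alone; adjusted p = 1.24e-21), with a median of -1.42 and NOP4 at -2.21 ± 0.21. Cytosolic ribosomal protein genes fell in 135 of 136 cases (135 adjusted over the list alone; adjusted p = 4.54e-30), with a median of -2.10 and RPL9A at -3.21 ± 0.43. The median was -1.57 and -1.77 on replicates 1 and 2 against -2.38 and -2.71 on replicates 3 and 4. RNA polymerase I and III genes fell in 23 of 24 cases (23 adjusted over the list alone; adjusted p = 8.31e-08), with RPA34 at -1.75 ± 0.60. These 3 lists had an adjusted p = 0.45 with an estimated correlation. Translation factor genes fell in 31 of 37 cases (33 adjusted over the list alone; adjusted p = 2.35e-06, and adjusted p = 0.789 with an estimated correlation), with medians of -0.52 and -0.69 on replicates 1 and 2 against -1.20 and -1.38 on replicates 3 and 4. Histone genes fell in 8 of 10 (9 adjusted over the list alone; adjusted p = 0.00251, and adjusted p = 0.714 with an estimated correlation). Genes of the G2, M and M/G1 phases fell in 13 of 22 cases (13 adjusted over the list alone; adjusted p = 0.00647, and adjusted p = 0.793 with an estimated correlation), with medians of -0.40 and -0.19 on replicates 1 and 2 against -0.58 and -0.50 on replicates 3 and 4. Mitochondrial ribosomal protein genes fell in 20 of 56, with 3 higher (15 and 3 adjusted over the list alone; adjusted p = 0.0406, or 0.0522 with replicates 1 and 2, and 3 and 4, averaged, and adjusted p = 0.897 with an estimated correlation). Fry did not call this list (adjusted p = 0.144), whose median was -0.16 and -0.16 on replicates 1 and 2 against -0.28 and -0.40 on replicates 3 and 4. The serine deaminase gene CHA1 was at -4.19 ± 0.04, and the glycolytic gene regulator RAP1 at -1.20 ± 0.15.

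In all, 3302 genes were called in glucose, 1512 higher and 1790 lower (1886 and 1943 with each array centred). Averaging replicates 1 and 2, and 3 and 4, before the fit left 1564.

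**Figure D2:**
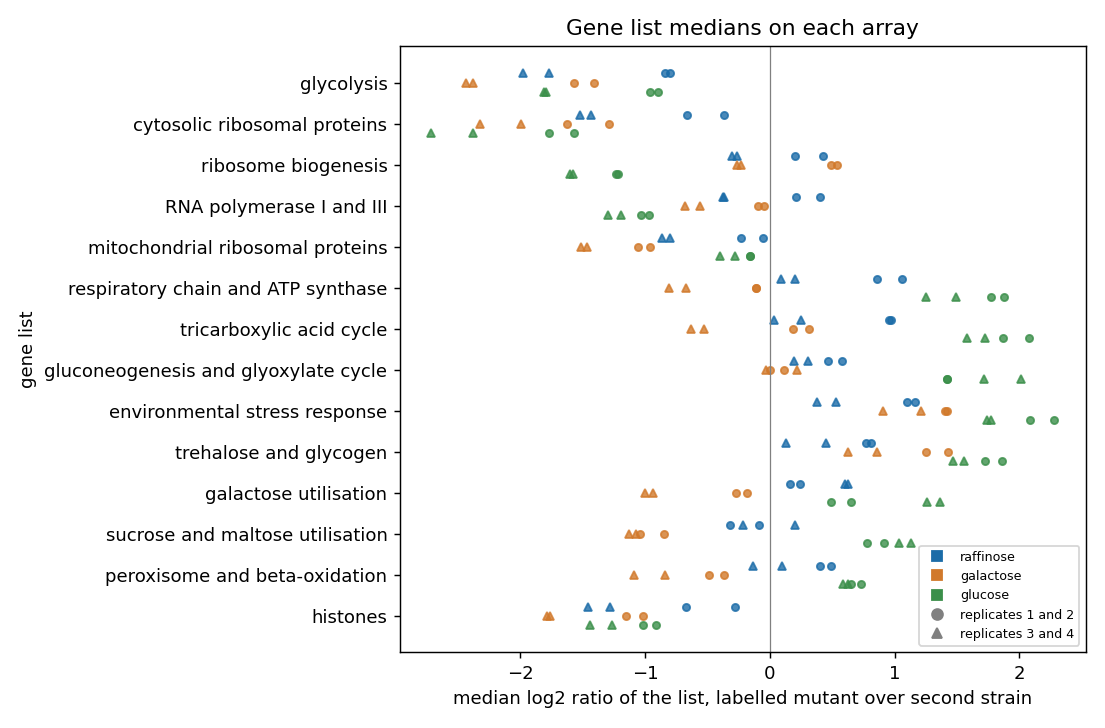
Median log2 ratio (labelled mutant over second strain, x axis) of 14 gene lists (y axis) on each of the 12 arrays; circles are replicates 1 and 2, triangles replicates 3 and 4. Respiratory chain medians lie above 0 in glucose and below 0 in galactose, and ribosome biogenesis medians lie furthest below 0 in glucose.

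The difference of the effect between raffinose and glucose was tested directly. In this and the other contrasts, higher or lower in a sugar refers to the ratio between the strains. Expression levels were not compared between sugars, and either strain's own response to the sugar can move the ratio. Ribosome biogenesis genes had a higher ratio in raffinose in 82 of 85 cases (84 adjusted over the list alone; adjusted p = 8.5e-25), and respiratory chain genes a lower one in 30 of 37 (35 adjusted over the list alone; adjusted p = 8.79e-13); with an estimated correlation both lists had an adjusted p = 0.487. The genes with the highest differences were CHA1 (4.28, SE 0.18), FRE4 (3.39, SE 0.51) and the mating genes FAR1 (2.44, SE 0.24), MFA1 (2.37, SE 0.22) and SST2 (2.31, SE 0.16). The lowest were the cell wall gene PIR3 (-4.96, SE 0.22), HSP12 (-4.62, SE 0.28), HXK1 (-4.45, SE 0.30), TPO2 (-4.19, SE 0.32) and PHO89 (-4.05, SE 0.19). Genes under nitrogen catabolite repression had a lower ratio in raffinose in 14 of 26 cases (15 adjusted over the list alone, camera adjusted p = 7.19e-08). This list held its call with an estimated correlation (camera adjusted p = 0.0308), but lost it when a term for the orientation was added as well. The galactose utilisation list, called lower in raffinose, and the pheromone list, called higher (adjusted p = 0.0391 and 0.0336), lost their calls with the replicate number as a block (adjusted p = 0.0585 and 0.0582; adjusted p = 0.582 and adjusted p = 0.487 with an estimated correlation). The first was lost too with arrays centred (adjusted p = 0.109), and the second with arrays averaged across the orientations (adjusted p = 0.145 and 0.147). The proteasome list was called higher with that block, although 2 of its 33 genes passed by themselves and 1 adjusted over the list alone (adjusted p = 0.0315, against 0.157; adjusted p = 0.875 with an estimated correlation).

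In this contrast 2117 genes were called, 1272 with a higher and 845 with a lower ratio in raffinose (1396 and 1418 with each array centred, which moved all differences by 0.136). The count was 3492 with the replicate number as a block, 132 with replicates 1 and 2, and 3 and 4, averaged, and 3713 or 4556 when averages crossed those pairs. With raffinose replicates 3 and 4 turned it was 2705, 1803 higher and 902 lower, of which 1503 were called in the same direction without turning. Both versions contain the same glucose effect, so this agreement is partly built in and does not bear on the signs.

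Between galactose and glucose, tricarboxylic acid cycle genes had a lower ratio in galactose in 15 of 18 cases, with a median difference of -2.22 (16 adjusted over the list alone; adjusted p = 2.07e-08, and adjusted p = 0.498 with an estimated correlation). Respiratory chain and ATP synthase genes had a lower ratio in galactose in 36 of 37 cases, with a median difference of -2.18 (36 adjusted over the list alone; adjusted p = 7.44e-19, and adjusted p = 0.376 with an estimated correlation). Ribosome biogenesis genes had a higher one in 70 of 85 (72 adjusted over the list alone; adjusted p = 3.61e-17, and adjusted p = 0.592 with an estimated correlation). The largest negative differences were those of TMA10 (-6.89, SE 0.25), HXK1 (-6.51, SE 0.30), RGI2 (-5.62, SE 0.32), the alcohol dehydrogenase gene ADH2 (-5.60, SE 0.24) and the lactate dehydrogenase gene CYB2 (-5.58, SE 0.30). The largest positive differences were those of RRP14 (4.30, SE 0.20), DIA1 (4.21, SE 0.39), BRE5 (3.92, SE 0.19), CMK2 (3.82, SE 0.45) and SPA2 (3.66, SE 0.24). Galactose utilisation genes had a lower ratio in galactose in 7 of 9 cases, with a median difference of -1.65 (7 adjusted over the list alone). This list had a camera adjusted p = 0.000247, and a camera adjusted p = 0.256 with an estimated correlation. With the replicate number as a block, the glycolysis and sulfur lists were also called lower in galactose (adjusted p = 0.0309 and 0.0443, against 0.0645 and 0.0859; adjusted p = 0.92 and adjusted p = 0.916 with an estimated correlation). Glycolysis genes were lower in 4 of 17 cases (4 adjusted over the list alone), and sulfur genes were lower in 5 of 28 and higher in 2, the same adjusted over the list alone. The cytosolic ribosomal protein and translation factor lists were called higher with that block (adjusted p = 0.0253 and 0.00897, against 0.252 and 0.0732; adjusted p = 0.922 and adjusted p = 0.92 with an estimated correlation). Of the 136 ribosomal protein genes 9 were higher and 1 lower (0 and 0 adjusted over the list alone), and their medians on replicates 1 to 4 were -1.62, -1.29, -2.32 and -1.996 in galactose against -1.57, -1.77, -2.38 and -2.71 in glucose. Translation factor genes were higher in 11 of 37 cases (7 adjusted over the list alone).

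In this contrast 2656 genes were called, 1568 with a higher and 1088 with a lower ratio in galactose (1586 and 1760 with each array centred, which moved all differences by 0.164). Averaging replicates 1 and 2, and 3 and 4, left 796, and averages that crossed those pairs gave 4089 or 4749.

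Between raffinose and galactose, peroxisome genes had a higher ratio in raffinose in 12 of 17 cases and a lower one in 2 (13 and 2 adjusted over the list alone; adjusted p = 1.39e-06, and adjusted p = 0.787 with an estimated correlation). Respiratory chain genes had a higher one in 28 of 37 and a lower one in 1 (32 and 1 adjusted over the list alone; adjusted p = 1.41e-10, and adjusted p = 0.828 with an estimated correlation). The highest single genes were RGI2 (5.72, SE 0.32), GCY1 (4.04, SE 0.32), FIT3 (3.64, SE 0.41), MRK1 (3.58, SE 0.26) and ATO2 (3.36, SE 0.17). The lowest were TPO2 (-7.18, SE 0.32), HSP30 (-4.65, SE 0.27), KTR2 (-4.54, SE 0.18), DIA1 (-4.37, SE 0.39) and CMK2 (-4.26, SE 0.45). The hexose transport list, called higher in raffinose, and the sulfur list, called lower (adjusted p = 0.0484 each), lost their calls with the replicate number as a block (adjusted p = 0.133 and 0.0563; adjusted p = 0.787 and adjusted p = 0.871 with an estimated correlation). The hexose transport call was lost too with arrays centred (adjusted p = 0.0975) or averaged across the orientations (adjusted p = 0.131 and 0.0941), and the sulfur call with arrays centred (adjusted p = 0.0755), with replicates 1 and 2, and 3 and 4, averaged (adjusted p = 0.0509) and by fry (adjusted p = 0.0588). The meiosis list was called lower with that block, with 5 of 37 genes lower and 1 higher, or 3 and 0 adjusted over the list alone (adjusted p = 0.0267, against 0.141; adjusted p = 0.871 with an estimated correlation), but its raffinose median was -0.59 and -0.67 on replicates 1 and 2 against 1.27 and 0.73 on replicates 3 and 4, and its galactose median -0.21 and 0.074 against 1.085 and 1.238.

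In this contrast 1718 genes were called, 751 with a higher and 967 with a lower ratio in raffinose (1480 and 1340 with each array centred). Without raffinose replicate 3 the split was 980 higher and 833 lower, and without galactose replicate 3 it was 456 and 838. The count was 3358 with the replicate number as a block, 84 with replicates 1 and 2, and 3 and 4, averaged, and 3561 or 4431 when averages crossed those pairs. With raffinose replicates 3 and 4 turned it was 2503, 1497 higher and 1006 lower, of which 1199 were called in the same direction without turning. The galactose effect is the same in both versions, so this agreement too is partly built in.

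**Figure D3:**
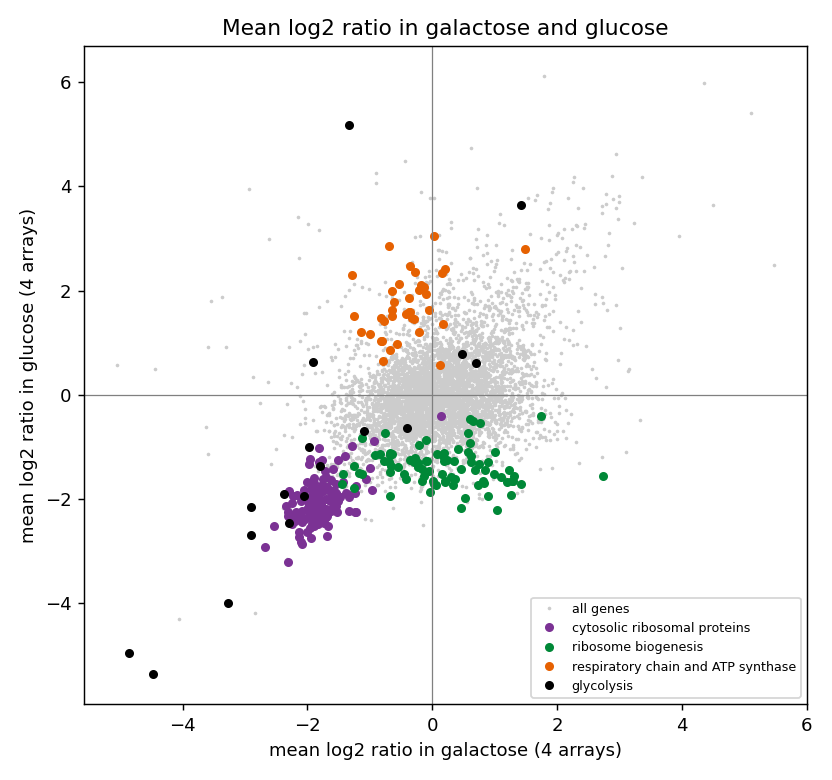
Mean log2 ratio of each of 5636 genes in galactose (x axis) and in glucose (y axis), each over 4 arrays, with 4 gene lists coloured. Cytosolic ribosomal protein genes lie low on both axes, ribosome biogenesis genes low in glucose (median -1.42) but around 0 in galactose (median 0.178), and respiratory chain genes high in glucose (median 1.59).

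Across the sugars, 877 genes were called in the same direction in all 3, 477 higher and 400 lower, against 118 and 64.5 for independent lists; GPM1, ENO1, ENO2, TDH3 and TPI1 were lower and GPM2 and URA3 higher in each. Raffinose and glucose shared 723 higher and 524 lower calls, against 339.4 and 256 for independent lists (2-sided Fisher's exact test over genes, p = 5.02e-154 and 1.42e-98). Raffinose and galactose shared 865 higher and 537 lower calls, against 440.4 and 203.2, and galactose and glucose 811 and 746, against 526.4 and 451.3. The calls of all sugars came from 1 fit with a shared spread per gene, so a gene with a small spread is easier to call in each. Genes that move together were also counted singly. The counts for independent lists are therefore a loose reference, and the Fisher p-values are too small to be read as given. Genes called in opposite directions numbered 658 between galactose and glucose, among them HXK1 and GAL1, 240 between raffinose and glucose and 162 between raffinose and galactose. For opposite calls no count for independent lists was worked out, so these numbers do not show an excess. The correlation of mean ratios across genes, which are not independent replicates, was r = 0.59 for raffinose with glucose, 0.589 for raffinose with galactose and 0.439 for galactose with glucose.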

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

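The tests of replicates 1 and 2 against 3 and 4, of GCR1 and of ribosomal protein genes were chosen only after the result was seen; those of the differences between sugars and of the splits and sign patterns were not.

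The effect differed between sugars, by the test of the difference itself, for 2117 genes between raffinose and glucose, 2656 between galactose and glucose and 1718 between raffinose and galactose. For the first 2 contrasts 1 of the 35 splits of the 8 arrays gave as many, the real one, and the highest other split gave 0. Over these 35 splits chance can be excluded if arrays are exchangeable, which numbered pairs and dye-swap repeats are not; 8 splits part all 4 pairs, too few for a share under 0.05. For raffinose and galactose 2 of 35 splits did, and chance cannot be excluded on that count: the split of replicates 1 and 2 against 3 and 4 called 3046 genes, more than the real 1718. That points to a structure of the arrays. The fit with the replicate number as a block called 3358 genes. Among the 8 splits that part all 4 numbered pairs, as the real one does, the highest other gave 0 in each contrast; the orientation split parts none of them. For the calls in single sugars, 1 of 8 sign patterns of the 4 arrays gave as many, the real one (2071, 3383 and 3302 genes). The others gave 0 at most, but 8 patterns are too few for a share under 0.05. A split or sign pattern that mixes arrays sharing an effect moves that effect into the spread. Counts of 0 there therefore do not measure how strong the real grouping is.

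The differences between raffinose and glucose included CHA1 (4.275), FRE4 (3.394), FAR1 (2.439), MFA1 (2.368), SST2 (2.309), PIR3 (-4.958), HSP12 (-4.625), HXK1 (-4.45), TPO2 (-4.186) and PHO89 (-4.053). Those between galactose and glucose included RRP14 (4.296), DIA1 (4.209), BRE5 (3.924), CMK2 (3.817), SPA2 (3.657), TMA10 (-6.895), HXK1 (-6.512), RGI2 (-5.62), ADH2 (-5.603) and CYB2 (-5.577). Those between raffinose and galactose included RGI2 (5.716), GCY1 (4.035), FIT3 (3.64), MRK1 (3.585), ATO2 (3.358), TPO2 (-7.178), HSP30 (-4.646), KTR2 (-4.539), DIA1 (-4.365) and CMK2 (-4.256). Lists called in opposite directions in galactose and glucose were galactose utilisation (median difference -1.65), sucrose and maltose utilisation (-2.13), the respiratory chain (-2.18; fry did not call it in galactose) and peroxisome and beta-oxidation (-1.57). With an estimated correlation none of these calls held (adjusted p = 0.715, 0.715, 0.958 and 0.715 in galactose and 0.472, 0.315, 0.45 and 0.505 in glucose), and that of galactose utilisation in galactose was lost on centring (adjusted p = 0.0879). The respiratory chain list was also called in opposite directions in raffinose and galactose (0.979), with an adjusted p = 0.989 and adjusted p = 0.958 at an estimated correlation. Its median was near 0 on raffinose replicates 3 and 4 (0.088 and 0.205) and on galactose replicates 1 and 2 (-0.1105 and -0.108).

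A single glucose array stood apart from the other 3 for CTT1 (replicate 2, by 0.863 of the range), HTA2 (replicate 4, 0.842) and RPL14B (replicate 4, 0.958); these were 3 of 292 tested, where chance gives about 5%. Probes without a gene name, outside the 114 extreme spots, were called in raffinose (32 of 1404), galactose (80) and glucose (90).

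Replicates 1 and 2 differed from replicates 3 and 4 in each sugar. Gene-specific dye bias needs the same genes to be shifted in every sugar, and the orientation effect correlated across genes at 0.77 or more between sugars, which is consistent with it. The 114 extreme unnamed spots changed sign between the pairs, which marks a change of orientation but does not show whether cultures differed too. Cultures that differ between the pairs would leave the difference of replicates 1 and 2 unrelated to that of 3 and 4. In galactose these differences correlated at 0.754, which argues against such cultures there. At 0.0823 in raffinose and 0.409 in glucose such cultures stay open and cannot be told apart from dye bias. No biological explanation was tested.

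The GCR1 probes read higher in the channel taken as the mutant. A single faulty spot is argued against, since the means of the 2 GCR1 probes differed by at most 0.112 in any sugar. Ratios that run the other way stay open: the glycolysis median was at most -1.37 in any sugar, which with textbook knowledge of Gcr1 argues against them, but GCR1 itself argues for them. Probes outside the deleted part, where a transcript may remain, stay open as well, because their positions are not known here; the glucose value was 0.402.

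Cytosolic ribosomal protein genes read lower in each sugar. With each array centred, the highest of the list's medians was -1.09. Centring shifted the sugars by only 0.0702 in raffinose, 0.0979 in galactose and -0.0663 in glucose. The array medians therefore do not account for the low ratios. A shift made by the authors' normalization, which is not given, cannot be seen this way and stays open. Paralogs sharing probes are argued against, since genes without an A or B copy had medians of at most -0.994. A growth-linked programme in which ribosome biogenesis genes fall as well would lower their median, which was -0.0095 in raffinose and 0.178 in galactose. The medians of single arrays differed in sign, however. They were 0.427 and 0.202 on raffinose replicates 1 and 2 against -0.302 and -0.2625 on replicates 3 and 4. In galactose they were 0.538 and 0.487 against -0.2625 and -0.235. A fall as large as the glucose median of -1.42 is argued against in both sugars, since no array median there lay below -0.302. The sign followed the orientation, so these values do not decide on a smaller fall in either sugar. On each of these arrays the median lay above that of the ribosomal protein genes. In glucose the ribosome biogenesis median was -1.42, consistent with such a programme as a hypothesis; growth rates were not analysed here.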

How the results depend on the processing

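Tests with an orientation term, turned signs, values over 10 set missing, and lists with the replicate number as a block were chosen after seeing the data; the others were planned. Counts of called genes are given for raffinose, galactose, glucose, raffinose minus glucose, galactose minus glucose and raffinose minus galactose, in that order where all 6 moved by over 1.5 times. Averaging replicates 1 with 2 and 3 with 4 gave 184, 1688, 1564, 132, 796 and 84. As a random block (correlation 0.875) they gave 455, 2034, 1893, 436, 1141 and 156. Both settings keep the orientation effect in the spread. Single probes gave 3233, 5491, 5356, 3437, 4318 and 2717, with more features tested. Calls of at least 2-fold numbered 418, 1308, 1267, 963, 1411 and 660. Averaging 1 with 3 and 2 with 4 gave 3660 in raffinose and 3713, 4089 and 3561 in the contrasts; 1 with 4 and 2 with 3 gave 4558, 4556, 4749 and 4431. The replicate block gave 3406 in raffinose and 3492 and 3358 in its contrasts with glucose and galactose. It moved no other count that far; of 101 list calls it ended 4, and it ended none of 536 calls of named genes. The orientation term gave 4075 in raffinose and 4097, 4384 and 4012 in the contrasts. At an adjusted p under 0.01, counts were 1330 in raffinose, 1326 and 983 in its contrasts, and 570 genes called alike in all sugars. Raffinose arrays alone gave 1233, and centring gave 2820 for raffinose minus galactose. Turned signs of replicates 3 and 4 gave 0 in each sugar, with 1463, 368 and 136 genes at an unadjusted p under 0.05; by construction this cancels effects shared by the orientations. For the same reason 41 of 76 called named genes changed sign in raffinose, with 0 called. Of the list calls, 0 held in any sugar with an estimated correlation, and 1, 0 and 0 in the contrasts; with an orientation term as well, 0 held. Fry called 17 lists in raffinose and 11 for raffinose minus galactose, and it ended 18 of the 101 list calls. Except where a limit or the construction shows it, the cause was not tested. Leaving out each array in turn gave 1575 to 2078, 2971 to 3467, 2833 to 3369, 1704 to 2194, 2319 to 2758 and 1294 to 1813 genes. Apart from turned signs, no called value of a named gene changed sign with centring or with single arrays left out. Averaged arrays, the replicate block and the orientation term leave the means of genes with all values unchanged, so no sign could change there. Leaving out an array of another sugar likewise does not move a sugar's mean. Calls of named genes were lost in 176 cases with 1 averaged with 2 and 3 with 4, and in 2 with centring. They were lost in 117 cases with an array left out, against 6315 kept, which include arrays of other sugars. Signal over background is unknown, which limits low-expressed genes.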

Other observations

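These observations were chosen after the values were seen. Some large ratios hardly varied with the sugar. In 19 genes the mean log2 ratio exceeded 2 in size in all 3 sugars and varied by less than 1 between them, out of 28 genes over 2 in all sugars. The uridine nucleosidase gene URH1 was at 2.217 in raffinose, 2.19 in galactose and 2.217 in glucose. The S-adenosylmethionine synthetase gene SAM1 was at -2.074, -2.117 and -2.07. The dicarboxylic amino acid permease gene DIP5 was at 2.455, 2.196 and 2.353, and COS8 at 2.395, 2.479 and 2.692. PET122, which encodes a translational activator of a mitochondrial message, was at -4.324, -4.058 and -4.316. URA3, a common marker gene, was at 2.64, 2.71 and 1.88, each with an SD of 0.111 or less; whether it marks the deleted locus is not given in the sources used here. The 7 strain marker genes as a list were not called by camera (adjusted p = 0.952, 0.843 and 0.516), which compares them with other genes. Fry, which does not, called them higher in each sugar (adjusted p = 1.82e-06, 7.9e-06 and 9.32e-06), although their median was -0.401 in raffinose and -0.341 in galactose.

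Regulators of glycolytic genes had ratios of different sign, and camera called their list of 15 genes in no single sugar (adjusted p = 0.318 in raffinose, 0.692 in galactose and 0.473 in glucose). Fry called it higher in raffinose (adjusted p = 0.0329, against 0.0927 and 0.122 in the others). TYE7, which encodes an activator of glycolytic genes, rose in each sugar, to 1.77 ± 0.47 in raffinose, 2.80 ± 0.29 in galactose and 1.63 ± 0.22 in glucose. GCR2, whose product partners Gcr1, was at 0.48 ± 0.32, 0.64 ± 0.23 and -0.59 ± 0.06; its raffinose call was lost without raffinose replicate 1 (adjusted p = 0.0563). The forkhead gene FHL1 and its partner gene IFH1, which act at ribosomal protein genes, fell in glucose to -0.84 ± 0.08 and -0.74 ± 0.02. FHL1 was at -0.22 ± 0.12 in raffinose and 0.12 ± 0.12 in galactose, neither called. IFH1 was at 0.37 ± 0.43 in raffinose, not called, and rose to 0.45 ± 0.46 in galactose. That call was lost without galactose replicate 1 or 2 (adjusted p = 0.197 and 0.169) or glucose replicate 2 or 3 (adjusted p = 0.0505 and 0.0508).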
